A study of Mus musculus with 4 samples.

How the data were processed

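ATAC-seq libraries of sorted lymph node FRCs from 2 genotypes, with 2 libraries each, were analysed. Each library was a pool of 6 female mice of 12 weeks, and the replicates are separate pools per the labels. Per the labels' protocols, 50000 sorted cells were tagmented for 30 min at 37 °C and amplified for 10 cycles. Per the submitters' processing notes, Trim Galore 0.6.7, cutadapt, Bowtie2 2.4.5, SAMtools 1.14, Picard 2.27.5 and deepTools were used with build mm10. The peak caller, the window filter, any shift of reads for the transposase and the csaw version are not given in the sources used here.

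The deposited table holds whole-number counts for 678058 overlapping windows of 300 bp, spaced by 50 bp. The labels call them loess-normalized, but the deposited counts summed over overlapping windows to 153282978, 167132696, 196562399 and 80428121 (control 1 and 2, Notch2_cKO 1 and 2), totals up to 2.44 times apart. They were checked for the gaps that scaling and rounding leave in a histogram. The measure was 1.04 to 1.14 in the deposited values, and 22.2 and 144.7 for the Notch2_cKO libraries if scaled by loess factors and rounded. The controls, at 0.936 and 2.15, gave this check little power. The values were therefore treated as counts without normalization. The design fixed before the data were examined assumed normalized peaks and limma. Because the table holds counts, edgeR's quasi-likelihood test was used for the main results, and limma became an alternative.

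Windows up to 100 bp apart were merged into 110121 regions (median width 600 bp), and the window with the highest mean level stood for each. Loess offsets in the manner of csaw, a trend of each library's log count on mean level, were computed with limma. edgeR fitted genotype without a replicate term, and p-values were adjusted by Benjamini and Hochberg at 0.05. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package in version 1.17.8, with Python and matplotlib for the figures. On simulated counts for the 110121 regions of this comparison, 13 of 67 regions changed 1.5-fold were recovered (19.4%), 42 of 67 changed 2-fold (62.7%) and 63 of 66 changed 4-fold (95.5%), with 6 false calls. In the simulation small changes were therefore often missed. Far fewer regions changed there than were called in the real data, which makes its adjusted threshold stricter. These shares and the 6 false calls therefore do not give the recovery or the error rate of the real comparison.

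Genes came from a RefSeq table of the same assembly (21792 protein-coding genes), without strand or genome sequence. A region was given the gene it overlaps, or else the nearest within 100000 bp, which 95460 regions had. This overlap, and the distances given for single regions, were taken from the midpoint of the window that stands for the region. Nearness does not show which gene a region acts on. A gene end, within 1000 bp of either end of a gene, took the place of a promoter. The 16 gene lists, and the rule for naming genes, were fixed before the data were examined. Named were Notch2 and Ccl19, the 10 genes of smallest p in each direction with both Notch2_cKO libraries beyond both controls, and up to 3 changed members of smallest p per list. A few items that this rule names are not reported here. Lists were tested with camera at a correlation of 0.01, adjusted over the 16 lists. With an estimated correlation no list passed. With fry, which asks whether a list's regions move one way on balance, Notch targets and lymphatic endothelial markers (adjusted p = 0.0451 each) and Notch pathway components, medullary and extracellular matrix genes (0.0469 each) passed.

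Members without an assigned region were not used here, among them Jag2, Ccl19, Ccl21a, Fdcsp, Fcer2a, Cxcl10, Timp1, Ifit1, Mx1, Psmb9, Cd79a, Cd79b and Itgax. Agreement within pairs was tested by chi-square per region, which was 1.89 between controls and 2.73 between Notch2_cKO libraries, against 10.1 between control 1 and Notch2_cKO 1, so no pair was counted as 1 library. Alternatives were other scalings, filters on level, other tests and thresholds, a replicate block, other distances to genes and each library left out. With 1 library left out, its group's lone library is assumed to vary like the other group. Motif sets and correction for GC content need a genome sequence and were not run.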

Results

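Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in fibroblastic reticular cells (FRCs) of mouse lymph nodes. FRCs are the fibroblasts that build the scaffold of the node and make chemokines for lymphocytes. The cells came from female C57BL/6 mice of 12 weeks and were sorted as BP3-high, podoplanin-positive, CD31-negative and CD45-negative cells, a gate meant to leave out endothelial cells and leukocytes. In 2 libraries the mice carried Ccl19-Cre with floxed Notch2 (Notch2_cKO), so that Notch2 is the gene targeted in cells with Ccl19-Cre activity. The other 2 libraries came from littermates with floxed Notch2 and no Cre (control). Each library was a pool of 6 mice with 50000 sorted cells. Summed over the best window of each of 110121 accessible regions, control replicates 1 and 2 held 23631019 and 25735845 counts, and Notch2_cKO replicates 1 and 2 held 30249562 and 12361844. Positions are in mm10, and distances of single regions from genes run from the midpoint of a region's best window. Levels are normalized CPM, counts scaled to library depth after loess adjustment, given as mean ± SD with n = 2 libraries. Changes are log2 of Notch2_cKO over control with an approximate standard error (SE). This SE was derived from edgeR's quasi-likelihood test, as the size of the change over the square root of the F statistic.

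The targeted gene was examined first. At Notch2, a receptor of the Notch family, the region at the gene's start (chromosome 3, 98013151 to 98013800) had 1361 and 1527 counts in the controls and 1636 and 542 in Notch2_cKO. Its normalized level was 56.4 ± 1.56 CPM in control and 50.7 ± 6.41 CPM in Notch2_cKO, a log2 change of -0.14 (SE 0.10) that did not pass the test (edgeR adjusted p = 0.339). Of 17 regions within 10000 bp of the gene, 5 were higher in Notch2_cKO, 1 was lower and 11 did not pass. The region with the largest rise lay inside the gene, from 98101601 to 98102200, with 1.38 ± 0.0636 CPM in control and 3.65 ± 0.451 CPM in Notch2_cKO (log2 1.44, SE 0.23, edgeR adjusted p = 0.000145). The lower one spanned 98108201 to 98108950, also inside the gene (log2 -0.79, SE 0.18, edgeR adjusted p = 0.00284). The count of higher regions depended on single libraries: 1 was higher without control replicate 1, 2 without control replicate 2 and 3 without Notch2_cKO replicate 1, while 2 were lower without Notch2_cKO replicate 1. The labels do not say which part of the gene is flanked by loxP sites, and no region beyond 98108950 was analysed here, so these values do not check the deletion.

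**Figure D1:**
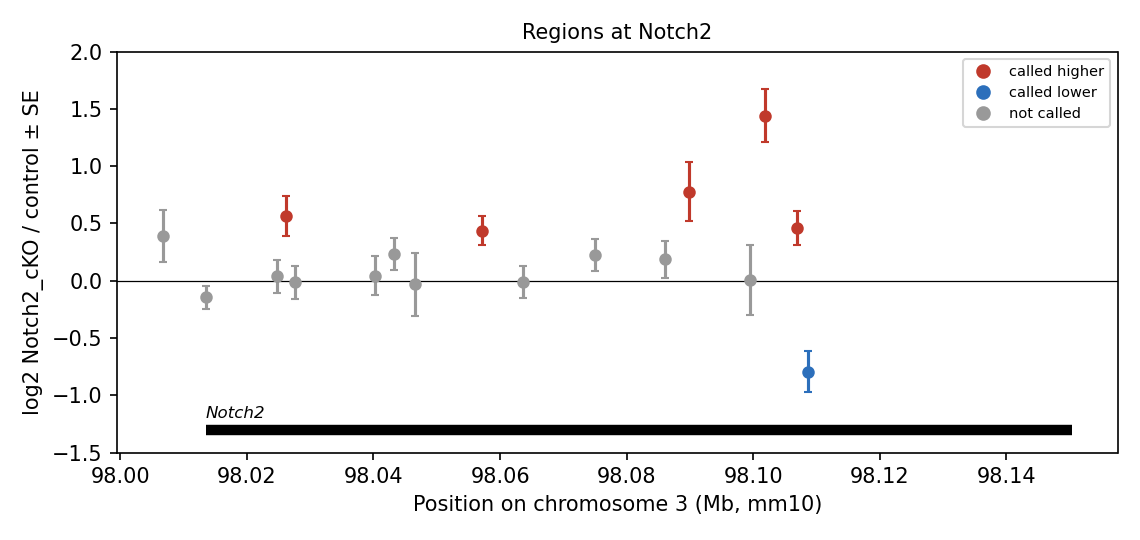
Log2 change in accessibility with its SE for the 17 regions at Notch2, against position on chromosome 3 (Mb); the black bar is the gene. Red, blue and grey points are the 5 regions called higher, the 1 called lower and the 11 not called.

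The Cre is driven from Ccl19 sequence, so the surroundings of Ccl19, which encodes a chemokine for T cells and dendritic cells, were examined as well. The nearest region began at 42852301 on chromosome 4, and the midpoint of its best window was 96085 bp from the gene. Closer positions, Ccl19 included, were not analysed here. Within 500000 bp there were 30 regions, of which 2 were higher and 1 was lower in Notch2_cKO. All of them lay on the same side of the gene, from 42852301 to 43246300, so its other side was not covered. Their median log2 change was 0.08, above 67.1% of the 109411 runs of as many neighbouring regions.

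Accessibility differed between the genotypes at 26127 of the 110121 regions (23.7%): 13790 were higher and 12337 lower in Notch2_cKO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes accounted for 6083 of the higher and 4823 of the lower regions. Among higher regions, one 30068 bp from Sfrp1, a secreted Wnt antagonist, rose from 0.509 ± 0.13 to 11.4 ± 0.143 CPM (log2 4.55, SE 0.24, edgeR adjusted p = 6.2e-10; chromosome 8, 23479401 to 23480000). A region inside Nt5e, which encodes the ectonucleotidase CD73, rose from 2.76 ± 0.0762 to 21.7 ± 1.71 CPM (log2 2.98, SE 0.17, edgeR adjusted p = 1.28e-09; chromosome 9, 88368401 to 88368950). A region 59976 bp from the survival gene Bcl2 rose from 7.66 ± 0.573 to 37.8 ± 0.0835 CPM (log2 2.31, SE 0.13, edgeR adjusted p = 1.46e-09; chromosome 1, 106477801 to 106478450). The other higher regions with the smallest p lay at or near Gm765, Sh3rf2, Syn3, Pank3, Myoc, Adamts15 and Skint6, with log2 changes from 3.24 to 3.99.

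Among lower regions, one inside Dcbld2 fell from 22.1 ± 1.95 to 3.36 ± 0.268 CPM (log2 -2.74, SE 0.17, edgeR adjusted p = 3.31e-09; chromosome 16, 58452901 to 58453600). A region 5881 bp from Elovl5, a fatty acid elongase, fell from 22.5 ± 0.646 to 4.54 ± 0.168 CPM (log2 -2.32, SE 0.15, edgeR adjusted p = 8.85e-09; chromosome 9, 77990151 to 77990750). A further 7 of the lower regions with the smallest p lay at or near Rab39, Slc35b3, Slc8a2, Fam189a1, Ccdc70, Vps35l and Mrpl39, with log2 changes from -3.73 to -1.82. Over all regions tested, both Notch2_cKO libraries lay beyond both controls on one side in 59.8%, against 33.3% by chance for 2 against 2. In this design the exact two-sided permutation p cannot go below 0.333, for a single region or for this share. The split depended on scaling: 52.8% of changed regions were higher with loess offsets and 40.8% when each library was centred on its median. Leaving out control replicate 2 gave 8917 higher and 8190 lower regions, and leaving out control replicate 1 gave 7991 lower ones. Control replicate 2 also held 221 counts at Ddx3y and 201 at Eif2s3y, both Y-linked, where the other libraries held 0, although all pools are labelled female.

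Regions at gene ends changed less often than other regions. Of 13449 regions within 1000 bp of an end of a protein-coding gene, 775 were higher (5.76%) and 603 lower (4.48%), whereas 13.5% of the regions within genes were higher and 11.5% lower. Gene ends made up 5.62% of higher regions against 13.2% of the rest (odds ratio 0.393, Fisher's exact test p = 4.09e-167), and 4.89% of lower regions against 13.1% of the rest (odds ratio 0.34, Fisher's exact test p = 3.92e-187). Neighbouring regions are not independent, so these p-values are too small. Single libraries moved both: the odds ratio for higher regions was 0.865 without Notch2_cKO replicate 2 and 0.251 without control replicate 1, and that for lower regions turned to 1.27 without Notch2_cKO replicate 1. At least 1 higher region was assigned to 5632 genes and at least 1 lower region to 4942, with 2240 genes in both sets. There were 1371 genes with 3 or more higher regions and 1051 with 3 or more lower regions. Without control replicate 2 these were 790 and 632, and without control replicate 1 the second was 574.

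Of 81 regions at 10 Notch target genes, 21 were lower in Notch2_cKO, 6 higher and 54 did not pass. As a list they stood lower than other regions with a preset correlation of 0.01 (camera adjusted p = 0.00892) but not with an estimated one (adjusted p = 0.431 with an estimated correlation). The call was also lost at a preset correlation of 0.05 (camera adjusted p = 0.399), with genes within 10000 bp (0.16) and at gene ends only (0.355). Of 56 regions at lymphatic endothelial markers, 8 were lower, 0 higher and 48 did not pass, and that list was also called lower only in some settings (camera adjusted p = 0.0406; adjusted p = 0.431 with an estimated correlation). At 7 of the 10 genes the changed regions were all lower, at Hes1 and Notch3 they went both ways, and at Dtx1 the 1 changed region was higher. Heyl, a transcriptional repressor induced by Notch, fell inside the gene from 5.11 ± 0.549 to 0.638 ± 0.00209 CPM (log2 -3.03, SE 0.26, edgeR adjusted p = 1.72e-07; chromosome 4, 123247151 to 123247600). Notch2_cKO replicates 1 and 2 held only 19 and 8 counts at Heyl, so the SD of 0.00209 does not give the precision. A region 36957 bp from Hes1, a repressor of the same family, fell from 19.3 ± 0.672 to 6.29 ± 0.319 CPM (log2 -1.61, SE 0.15, edgeR adjusted p = 3.3e-07; chromosome 16, 30028101 to 30028700). A region inside Jag1, which encodes a Notch ligand, fell from 10.6 ± 1.16 to 5.01 ± 0.0343 CPM (log2 -1.08, SE 0.17, edgeR adjusted p = 8.86e-05; chromosome 2, 137097051 to 137097650). Adjusted over the list alone, 23 regions were lower and 6 higher. Among 163 regions at Notch pathway components, 15 were higher and 27 lower (15 and 28 adjusted over the list alone). The list did not pass camera (camera adjusted p = 0.282) but passed fry (fry adjusted p = 0.0469). With median centring the counts were 9 and 36. At Rbpj, the DNA-binding partner of Notch, 5 regions were lower and 1 higher, the higher one having the smallest p (log2 1.85, SE 0.18). At the ligand gene Dll1 4 were lower and 1 higher, again with the smallest p in the higher one (log2 2.23, SE 0.31). At Lfng, a glycosyltransferase that modifies Notch, 2 were higher and 0 lower (log2 1.16, SE 0.16 at that of smallest p).

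**Figure D2:**
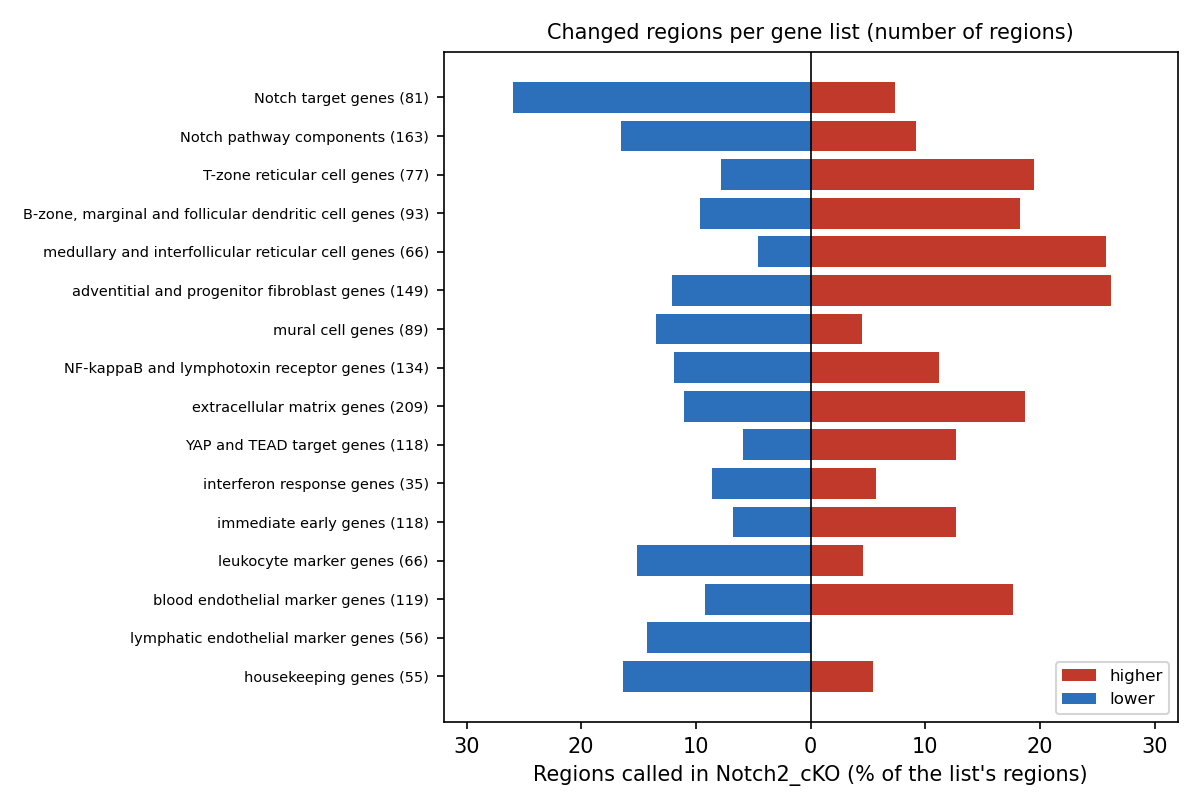
Share of each list's regions called higher (red, right) or lower (blue, left) in Notch2_cKO, in percent of the list's regions, whose number stands in brackets. Notch target genes had 21 lower and 6 higher regions of 81, and adventitial and progenitor fibroblast genes 39 higher and 18 lower of 149.

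Of 66 regions at 8 measured genes of medullary and interfollicular reticular cells, 17 were higher, 3 lower and 46 did not pass (18 higher and 3 lower adjusted over the list alone). Of the higher regions 7 were assigned to Cxcl12 and 5 to Gdf10, each with 1 lower region. Apod and Tnfsf10 had 1 changed region each. As a list they stood higher than other regions with the preset correlation (camera adjusted p = 0.00892) but not with an estimated one (camera adjusted p = 0.431). The list also passed fry (fry adjusted p = 0.0469). The camera call was lost too with genes within 10000 bp (camera adjusted p = 0.545), at gene ends only (0.885) and with a preset correlation of 0.05 (0.399). It was lost as well with the lowest 25% of regions left out (0.0556) and without Notch2_cKO replicate 1. A region 5142 bp from Apod, a lipocalin, rose from 3.88 ± 0.382 to 11.1 ± 0.812 CPM (log2 1.53, SE 0.17, edgeR adjusted p = 2.52e-06; chromosome 16, 31290751 to 31291350). A region 5977 bp from Tnfsf10, which encodes the death ligand TRAIL, rose from 4.55 ± 0.00604 to 11.5 ± 0.215 CPM (log2 1.34, SE 0.16, edgeR adjusted p = 5.82e-06; chromosome 3, 27310801 to 27311450). A region 18482 bp from the chemokine gene Cxcl12 rose from 3.62 ± 0.0062 to 8.94 ± 0.585 CPM (log2 1.32, SE 0.17, edgeR adjusted p = 1.5e-05; chromosome 6, 117199501 to 117200150). This Cxcl12 region lay in a higher block of 36 neighbouring regions, from 116829201 to 117314150 (median log2 0.48, blocks below). The higher regions at Cxcl12 may therefore not be separate changes.

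Of 149 regions at 15 adventitial and progenitor fibroblast genes, 39 were higher, 18 lower and 92 did not pass (45 higher and 21 lower adjusted over the list alone). As a list they stood higher with the preset correlation (camera adjusted p = 0.0406) but not otherwise (adjusted p = 0.602 with an estimated correlation). Inside Efemp1, which encodes a matrix glycoprotein, a region rose from 3.66 ± 0.0635 to 16.9 ± 3.51 CPM (log2 2.24, SE 0.18, edgeR adjusted p = 5.77e-08; chromosome 11, 28909051 to 28909650). At Efemp1 as a whole 6 regions were higher and 1 lower. At Fbn1, the fibrillin-1 gene, 6 regions were higher and 8 lower, that of smallest p being higher (log2 2.33, SE 0.20). At the semaphorin gene Sema3c 4 were higher and 2 lower, that of smallest p again higher (log2 2.44, SE 0.24). The call was also lost with genes within 10000 bp (camera adjusted p = 0.0694), with a preset correlation of 0.05 (0.594) or without Notch2_cKO replicate 2. It was lost too without chromosome 11 (camera adjusted p = 0.0915), an alternative chosen after the data were seen. All 14 of the list's regions on chromosome 11 were assigned to Efemp1, which lies before the part of that chromosome that was higher as a whole (below). This alternative thus took Efemp1 out of the list and does not test that rise.

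**Figure D3:**
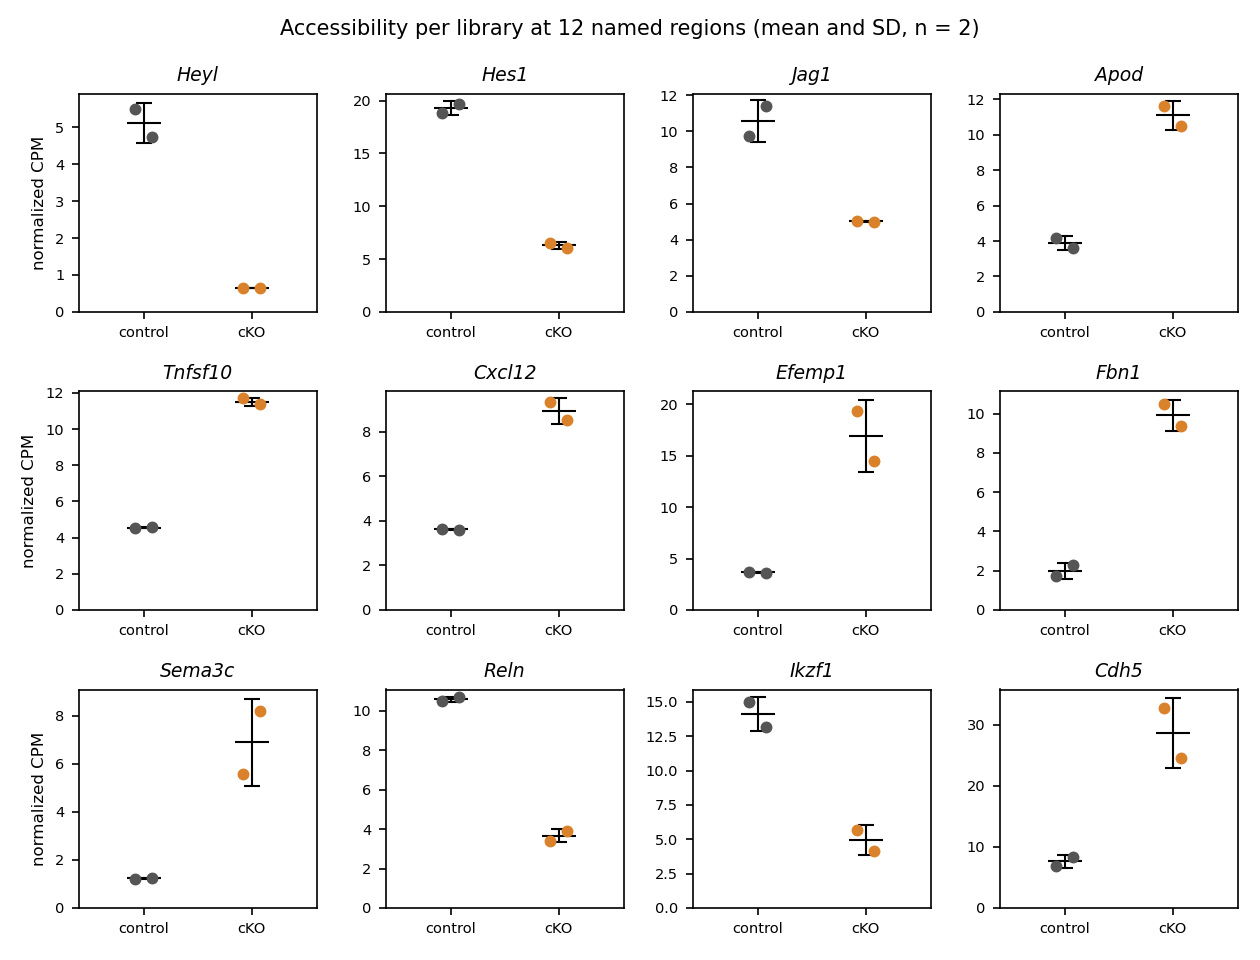
Normalized CPM of each library (points) with mean and SD (n = 2) for control (grey) and Notch2_cKO (orange) at 12 named regions, each axis starting at 0. Heyl, Hes1, Jag1, Reln and Ikzf1 regions were lower and the other 7 higher in Notch2_cKO.

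The following lists did not pass camera, although extracellular matrix genes passed fry (fry adjusted p = 0.0469). The members named are single regions of smallest p, and other regions of the same genes can go the opposite way. T-zone reticular cell genes, with Ccl19 and Ccl21a not analysed here, had 15 higher and 6 lower of 77 regions (15 and 7 adjusted over the list alone, camera adjusted p = 0.282). Among them were higher regions near Tnfsf13b, the BAFF gene (log2 0.98, SE 0.21), and 95140 bp from the interleukin gene Il7 (log2 0.76, SE 0.20). A region inside Il33 was lower (log2 -0.66, SE 0.16), where 3 regions were higher and 2 lower. With median centring the T-zone counts were 10 and 8, and with TMM 11 and 7. Genes of the B zone, marginal and follicular dendritic cells had 17 higher and 9 lower of 93 (22 and 9 adjusted over the list alone, camera adjusted p = 0.178). A region at an end of Sostdc1 rose (log2 1.15, SE 0.15). Single regions fell at Clu (log2 -0.99, SE 0.14) and Enpp2 (13.1 ± 1.67 to 6.78 ± 1.58 CPM), although 7 regions were higher and 4 lower at Enpp2. At Sox9, in the part of chromosome 11 that was higher as a whole (below), 6 regions were higher and 0 lower. Extracellular matrix genes had 39 higher and 23 lower of 209 (41 and 23 adjusted over the list alone, camera adjusted p = 0.147). Regions rose inside Tnc (log2 1.41, SE 0.18) and 42650 bp from Dcn (log2 1.31, SE 0.17), and a region fell inside Mmp2 (log2 -1.13, SE 0.19). With median centring the counts were 33 and 31. NF-kappaB and lymphotoxin receptor genes had 15 higher and 16 lower of 134, the same counts adjusted over the list alone (camera adjusted p = 0.828), with a rise near Tnfaip3 (log2 1.26, SE 0.16) and falls near Nfkb1 (log2 -1.28, SE 0.21) and Birc3 (log2 -0.94, SE 0.16). At Tnfaip3 3 regions were higher and 5 lower, and at Nfkb1 2 and 2. At Map3k14, in the part of chromosome 11 that was higher as a whole (below), 8 regions were higher and 0 lower. Without chromosome 11, an alternative chosen after the data were seen, the list did not pass either (camera adjusted p = 0.421). With median centring the list had 13 higher and 26 lower. YAP and TEAD target genes had 15 higher and 7 lower of 118, the same counts adjusted over the list alone (camera adjusted p = 0.594), with falls inside Wwtr1 (log2 -1.44, SE 0.18) and Axl (log2 -1.77, SE 0.24) and a rise near Amotl2 (log2 1.67, SE 0.23). At Wwtr1 5 regions were higher and 3 lower. With median centring the list had 15 higher and 15 lower. Immediate early genes had 15 higher and 8 lower of 118 (15 and 7 adjusted over the list alone, camera adjusted p = 0.572), with rises near Jun (log2 1.64, SE 0.18) and Atf3 (log2 1.31, SE 0.17) and a fall near Ier3 (log2 -1.49, SE 0.19). With median centring the list had 14 higher and 21 lower, and its direction turned downward there and with TMM. Interferon response genes had 2 higher and 3 lower of 35 (1 and 2 adjusted over the list alone, camera adjusted p = 0.997), with a higher region at Irf7 (log2 0.35, SE 0.12) and a lower one near Irf1 (log2 -0.72, SE 0.19).

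Markers of endothelial cells and leukocytes, which the sort gate was meant to leave out, were measured in the same way. So were mural cell and housekeeping genes. Lymphatic endothelial markers had 8 lower and 0 higher of 56 regions at 7 genes, also adjusted over the list alone (camera adjusted p = 0.0406; adjusted p = 0.431 with an estimated correlation). The lower regions were assigned to Reln, Stab2 and Mmrn1. Those of smallest p lay inside Reln (log2 -1.56, SE 0.17), inside Stab2 (log2 -1.04, SE 0.27) and 88272 bp from Mmrn1 (log2 -1.09, SE 0.29). The Reln region lay in a lower block of 27 neighbouring regions on chromosome 5 (median log2 -0.6, blocks below). The list did not pass without control replicate 1 or without Notch2_cKO replicate 1 or 2. The call was also lost with genes within 10000 bp (camera adjusted p = 0.118), a preset correlation of 0.05 (0.524), median centring (0.119), TMM (0.105) and the lowest 25% of regions left out (0.109), and at gene ends only the direction turned upward (0.914). Leukocyte markers had 3 higher and 10 lower of 66, also adjusted over the list alone (camera adjusted p = 0.245), with falls near Ikzf1 (log2 -1.47, SE 0.17) and inside Lcp2 (log2 -1.73, SE 0.23) and a rise inside Cd247 (log2 1.12, SE 0.18). Blood endothelial markers had 21 higher and 11 lower of 119 (23 and 14 adjusted over the list alone, camera adjusted p = 0.662). Regions rose 78363 bp from Cdh5 (log2 1.93, SE 0.16) and near Flt1 (log2 1.42, SE 0.14) and Tek (1.1 ± 0.23 to 5.13 ± 0.585 CPM). The median (-0.02) and mean (0.06) of this list differed in sign, and with median centring 18 were higher and 16 lower. Mural cell genes had 4 higher and 12 lower of 89 (4 and 10 adjusted over the list alone, camera adjusted p = 0.572). Regions rose near Kcnj8 (log2 1.88, SE 0.26) and inside Rgs5 (log2 1.40, SE 0.21), and a region fell near Mcam (log2 -0.79, SE 0.14). Of the 13 mural cell genes, 8 had only lower changed regions, 1 only higher, 1 both and 3 none. Housekeeping genes had 3 higher and 9 lower of 55 (2 and 9 adjusted over the list alone, camera adjusted p = 0.38), the 3 of smallest p being lower regions nearest to Ywhaz, Actb and Hprt (log2 -2.07, -1.05 and -0.99). The Hprt region lay in a lower block of 37 neighbouring regions on chromosome X (median log2 -0.29, blocks below). Medians and means also differed in sign for housekeeping genes (0.02 and -0.08) and for NF-kappaB and lymphotoxin receptor genes (0.01 and -0.01), and interferon response genes had a median of 0.00 and a mean of 0.04 although camera placed them lower.

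Changed regions were also clustered along the chromosomes. Runs of 25 neighbouring regions with a median log2 change beyond 0.58 formed 43 higher and 65 lower blocks, against at most 3 and 1 in 100 random orders. Of the 43 higher blocks, 11 lay on chromosome 11, and the longest there held 164 regions from 66168251 to 68897600 (median log2 0.63). Chromosome 11 had a median log2 change of 0.24 over 6608 regions, and 1337 of its 1714 changed regions were higher, whereas no other chromosome had a median above 0.06. The point that best divided the chromosome by least squares, chosen from these same values, lay at 44.3 Mb, so the contrast across it is in part built in. Beyond it the median was 0.30 over 4872 regions, and before it 0.01 over 1736. Without Notch2_cKO replicate 2 the lower blocks numbered 112.

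**Figure D4:**
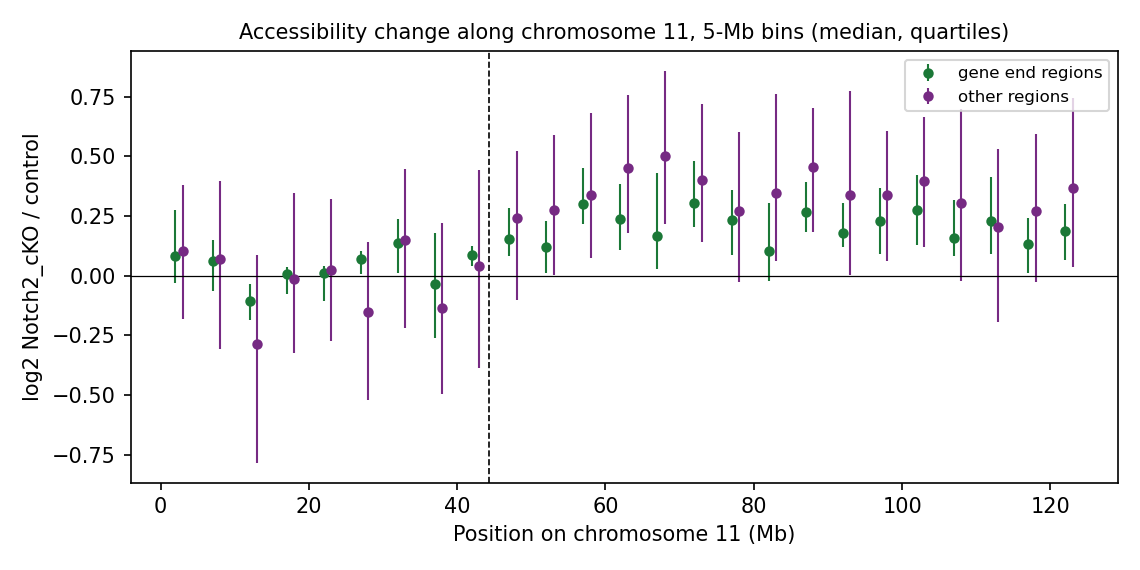
Median log2 change with quartiles in 5-Mb bins along chromosome 11, for regions at gene ends (green) and others (purple); the dashed line marks 44.3 Mb, the dividing point chosen from these values. Medians over all regions were 0.01 before and 0.30 beyond this line.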

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

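The test of every window, Simes' method, TMM, median centring for the lists, the fits without chromosome 11 and all alternatives for blocks were chosen after the data were seen. Depth and 2 libraries per group limit every count, and where no reason is given the cause was not tested. Against 13790 higher and 12337 lower regions, there were 7000 and 5854 with only the upper 50% of regions by level, where fewer regions were tested, 7832 and 6712 with limma without trend, 7371 and 5477 with DESeq2, 8548 and 7046 at adjusted p under 0.01, and 83233 and 73237 when every window was tested, which counts overlapping windows. Each library left out in turn gave 8917 to 15490 higher and 7991 to 14722 lower regions. Median centring gave 12175 and 17647. The remaining alternatives stayed within 1.5 times. Odds ratios at gene ends were 0.251 to 0.865 for higher and 0.262 to 1.27 for lower regions with 1 library left out, the 1.27 being without Notch2_cKO replicate 1. Genes with 3 or more regions numbered 862 higher and 650 lower within 10000 bp, and 790 to 1541 and 574 to 1295 with 1 library left out. Higher regions at Notch2 ranged from 1 to 5 and lower ones from 1 to 2 with 1 library left out, where each group's lone library adds to the uncertainty. Higher blocks ranged from 31 to 63 and lower ones from 45 to 112. The median near Ccl19 ranged from -0.05 to 0.20.

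Of the lists, Notch targets lost the call with an estimated correlation (adjusted p = 0.431), at 0.05 (0.399), within 10000 bp (0.16) and at gene ends only (0.355), and ranged from 0.000795 to 0.014 with 1 library left out. Medullary genes lost it under the same settings (0.431, 0.399, 0.545 and 0.885) and without the lowest 25% by level (0.0556), and ranged from 0.0067 to 0.0598. Adventitial genes lost it with an estimated correlation (0.602), at 0.05 (0.594), within 10000 bp (0.0694) and without chromosome 11 (0.0915), and ranged from 0.00755 to 0.201. Lymphatic markers lost it with an estimated correlation (0.431), at 0.05 (0.524), within 10000 bp (0.118), with median centring (0.119), TMM (0.105) and without the lowest 25% by level (0.109), turned upward at gene ends only (0.914), and ranged from 0.0327 to 0.0701. No other list passed camera under any alternative run.

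The labels do not say that a replicate number marks a shared litter or day, and deviations of the same-numbered libraries correlated at -0.139 over regions. With the replicate block 12235 regions were higher and 10782 lower, and the 4 list calls stood. Of 1064 alternatives for 68 named regions, 1038 kept direction and side of the threshold, 26 no longer passed and 0 turned. These regions were named for their small p, and every alternative used the same libraries, so this is largely built in. It does not carry over to the other changed regions. GC correction, motif sets and pseudocounts were not run.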

Other observations

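The tests of chromosome 11, of Y-linked counts and of endothelial markers were chosen only after the results were seen. The Wnt, BMP and Hedgehog lists were prompted by genes already seen, which were left out of them, and their tests were fixed before their results, to be read from the unadjusted p; adjusted values over the 3 lists are given, and no list passed by either.

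Several genes gathered many changed regions of one direction; they were chosen after their values were seen, and long genes hold more regions. At Smoc2, a secreted matrix-associated protein, 14 of 23 regions were higher and 0 lower, at Sfrp1 13 of 22 and 0, and at Adam12, a metalloprotease, 11 of 38 and 0. At Cyria 17 of 35 regions were lower and 0 higher, at Plac1 14 of 18 and 0, and at the phosphodiesterase gene Pde3a 12 of 32 and 0. The Sfrp1 region named in the Results lay in a higher block of 32 neighbouring regions (median log2 0.41). Such counts per gene and the blocks can thus describe the same stretches. Without Sfrp1, Ror2, Bmper and Gli2, Wnt pathway genes had 41 higher and 25 lower of 305 regions, and the hypothesis that they moved one way did not pass (limma's camera, adjusted p = 0.425). BMP pathway genes had 21 higher and 27 lower of 227 (limma's camera, adjusted p = 0.796). Hedgehog pathway genes had 15 and 8 of 104 (limma's camera, adjusted p = 0.41). Single members changed strongly, as near Sfrp4 (log2 1.52, SE 0.17) and Id2 (log2 -2.74, SE 0.34).

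Regions on chromosome 11 beyond 44.3 Mb, a point chosen from the same values, were higher in Notch2_cKO by log2 0.30 against other autosomes, and by 0.30 to 0.33 with quantile, median and TMM scaling. Relative to the mean of all libraries they stood at -0.14 in both controls, 0.22 in Notch2_cKO replicate 1 and 0.07 in replicate 2. A trend with gene density predicted 0.067, which argues against it as the whole cause. Highly accessible gene ends beyond the point were higher too (median 0.188, interval 0.153 to 0.227, other autosomes at most 0.04). Their values helped to choose the point, and the other autosomes were taken whole, so this gap is in part built in. A change at a part of the elements therefore stays open. Extra copies in some cells, as the whole cause, would shift gene ends and other regions alike, but gene ends shifted less, by -0.127 (interval -0.177 to -0.093). Copies together with another difference, GC content and regulation across the chromosome by genotype stay open and untested.

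Control replicate 2 may hold cells of a male animal. At 5 single-copy Y-linked genes the other libraries held on average 0.101% of its counts, which argues against repeated Y sequence. From 3 pairs of Y-linked genes and X-linked partners, assuming equal accessibility per copy, the male share was 30.7% (Eif2s3y), 10.4% (Uty) and 9.57% (Kdm5d), mean 16.9%, and 1 of 6 mice would give 16.7%. The pairs differ widely, this test was rewritten after a first version had matched the wrong regions, and DNA from another male library stays open. The design names no biological explanation for these counts, and none by genotype was tested.

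Some regions at blood endothelial markers rose in Notch2_cKO although CD31-positive cells were gated out. Endothelial cells in the pools would raise these regions together, but 65.6% of the changed ones were higher (interval 38.5 to 84.8, genes resampled), below a bound of 90% that was set after the counts were seen. This argues only against such cells as the cause of all the changed regions, 11 of which were lower. Such cells as a source of the 21 higher regions, and a difference by genotype in the reticular cells, stay open and untested.

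Regions more than 500000 bp from a protein-coding gene had a median log2 change of -0.25, with 206 higher and 488 lower of 2352.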
